A study of Mus musculus with 556 samples.

How the data were processed

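The data are single-cell DamID profiles of mouse oocytes, preimplantation embryos and embryonic stem (ES) cells. In DamID a bacterial adenine methyltransferase, Dam, is fused to a nuclear protein and the DNA that it methylates is amplified and sequenced. The protein here was lamin B1, a component of the nuclear lamina under the inner nuclear membrane, so Dam-lamin B1 marks lamina-associated domains (LADs). Dam alone marks accessible chromatin and served as the control. Per the labels' protocols, mRNA for Dam or Dam-lamin B1 carrying an auxin-inducible degron was injected into oocytes and embryos, and auxin was withheld for 6 to 8 h so that methylation was restricted to the stage of interest. The labels give 5 ng/µl of Dam-lamin B1 mRNA for oocytes and zygotes, 10 ng/µl for 2-cell and 20 ng/µl for 8-cell embryos, and 20 or 40 ng/µl of Dam mRNA. The doses therefore differ between stages and constructs. No dose of Dam-lamin B1 mRNA is given for zygotes with Kdm4d, aphidicolin or DMSO, or for pronuclei without Kdm5b. Kdm5b mRNA, wild type or mutant, was given at 2 µg/µl. The dose of Kdm4d mRNA and when zygotes received aphidicolin or its solvent DMSO are not given in the sources used here, nor is what the mutations change. The strain label is C57BL/6 for oocytes and isolated pronuclei, a cross with CAST/EiJ males for whole zygotes, 2-cell and 8-cell embryos, and another CAST/EiJ cross for ES cells. It is the same for both groups of each tested comparison and differs between stages.

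The series holds 556 samples. Each sample was placed in a group from its title or its other labels. The deposited table holds values for 512 cells, of which 360 with Dam-lamin B1 and 138 with Dam alone had a group. The other 14 cells have labels that contradict each other: 13 oocytes carry both a 20 ng and a 50 ng label, and 1 cell of an 8-cell embryo carries both constructs. These 14 cells entered no comparison. Samples made from pools of 15 to 24 cells, whole ICM or whole TE were not used here.

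The deposited table gives a ratio of observed to expected reads (OE) for each cell in 24639 autosomal bins of 100 kb, in build mm10 per the submitters' processing notes. Bins without a value in the table, 617 in number, were left out, which left 24022 bins. How the expected number was made is not given in the sources used here. The submitters' processing notes name cutadapt and BWA 0.7.12, with no order or settings. The authors also deposited LAD coordinates, 1 list for the inner cell mass (ICM) and 1 for the trophectoderm (TE) of the blastocyst. These lists hold intervals without a score or other value, and how the LADs were called is not given in the sources used here.

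The OE ratio hides the depth, so the depth was recovered. Within a bin, the OE values of a cell are whole multiples of what 1 read is worth, and the size of that step was estimated over the 60 cells with the most empty bins. The step was found for 23954 bins. With a tolerance of 0.02 reads, between 98.0% and 99.96% of the lower non-zero values of a cell came out as whole reads. Higher values were not part of this share, and the step was chosen to make it high. In deep cells it therefore covers a smaller part of the values. Depth by this estimate ran from 48487 to 5105041 autosomal reads per cell, with a median of 247139. On simulated cells the recovery gave exact reads for over 99% of the bins in 100% of cells. The simulated cells did not reach the reads per bin of the deepest real ones. These depths are estimates: were the smallest step worth several reads, the depth would be a multiple of them. PCR reads without molecular identifiers are not independent molecules. Intervals on shares of cells take the cells as independent draws and cover counting error only.

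The main measure per cell was the LAD contrast, the log2 of the mean OE over bins covered at least 50% by both LAD lists divided by the mean OE over bins touched by neither. Groups were compared by a 2-sided permutation test of the difference of means, exact where a group held under 10 cells and with 100000 resamples otherwise. The smallest p these resamples can give is 1e-05. Intervals of differences are 95% bootstrap intervals. Whether the Kdm5b effect differs between pronuclei was tested by permuting the parental labels within the wild-type and within the mutant cells. Kdm5b was set against Kdm4d in the same way. This supposes no parental or demethylase difference at all, so a difference shared by wild type and mutant also enters these p-values. The p-values of the LAD contrast were Benjamini-Hochberg adjusted over the 7 comparisons. The same test was applied to 5 further measures per cell, adjusted together over 35 tests: the share of bins with OE of at least 1, the autocorrelation of OE along chromosomes at lags of 1 and 10 bins, and Pearson's r across bins with the mean ES-cell profile and with gene density. The r with the mean profile of zygotes that received Dam was added after seeing the data. A cell was left out of a mean profile it was compared with.

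Bins that differed between groups were found with limma 3.58.1 (trend and robust options) on log2(OE + 0.25), among bins with a mean OE of at least 0.1, at a Benjamini-Hochberg adjusted p under 0.05. Differences of bins are on this scale, which understates the change of bins with low OE. As simulated data, 100 bins in each comparison were changed 4-fold and another 100 were changed 2-fold. In the zygote comparison of Dam-lamin B1 and Dam, over 23956 bins, limma recovered 87 of the 4-fold and 25 of the 2-fold changes with 4 false calls. In the other 6 comparisons it recovered 0 to 3 of the 2-fold changes with 0 to 6 false calls, and the 4-fold numbers stand beside their results. Simulated groups drawn without a difference gave a permutation p under 0.05 in 2% of sets, and shifted groups in 92%.

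Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 names. The plan called for transcription start sites, but the table used here has no strand, so each gene was placed in the bin that holds its midpoint. AT content was planned as a further measure and was not analysed here because no genome sequence was used. There were 20 gene lists: olfactory receptors, vomeronasal receptors, defensins, keratins and keratin-associated proteins, clustered protocadherins, Hox clusters, canonical histone clusters, ribosomal proteins, the prolactin family, cytochrome P450 families, Zfp zinc finger genes, long neuronal adhesion and synapse genes, pluripotency, trophectoderm, primitive endoderm, oocyte, zygotic genome activation, housekeeping, lamina and its tethers, and a set of 28 marker genes. A list score is, per cell, the log2 of the mean OE over the bins of a list divided by the mean over all bins, with 0.05 added to both, a constant that the plan did not name. List scores were tested as the LAD contrast was, adjusted over the 20 lists within a comparison. A score rests on mean OE and a median over bins on log values, so they can differ in sign. Some lists are gene clusters that fill few bins, such as 25 prolactin genes in 14 bins and 39 Hox genes in 9. OE is correlated along chromosomes, so neighbouring bins of such a list are not independent.

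Groups, tests, gene lists, the choices to be varied and the rule for named genes were fixed before the data were examined. The rule takes the 28 marker genes, and for each tested comparison up to 10 called bins with the largest positive and up to 10 with the largest negative difference, 1 per 1 Mb, with at most 3 protein-coding genes in each. Some of the bins this rule takes are not reported here. For each step from oocyte to ES cell it takes, likewise, the 10 bins with the largest rise and the 10 with the largest fall in contact frequency, which is the share of cells with OE of at least 1 in a bin. Contact frequency was averaged over 100 draws of 10 cells, so that groups of different size compare. Cells of animals or cultures that the labels do not name are not replicates. For oocytes, blastomeres and ES cells the text therefore gives means and SDs over cells with no test.

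The choices varied as planned were the pseudocount, the filter on low OE, the scaling of each cell, the size of the bins, the test per bin, the LAD list, the share of a bin a LAD must cover, a cap on OE of 5, the summary of OE, the contact threshold and the use of replicate numbers as blocks. A filter on cells with under 25% of bins above 0 removed 0 cells. Alternatives added after seeing the data drew the same 45000 reads from each cell, or as many reads as the shallowest cell of both groups holds. Overlaps of LADs were computed with bedtools 2.31.1 at a minimum of 1 bp. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3.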

Results

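Lamina contacts were mapped in single cells from the oocyte to the 8-cell embryo, in ES cells, and in zygotes and pronuclei under several treatments. With Dam-lamin B1 the groups held 56 oocytes, 17 oocytes labelled 20 ng and 23 labelled 50 ng, 19 zygotes, 47 cells of 2-cell embryos, 41 cells of 8-cell embryos and 10 ES cells. With Dam alone they held 43 oocytes, 46 zygotes, 45 cells of 2-cell embryos and 4 of 8-cell embryos. Zygotes with Dam-lamin B1 also received Kdm5b, wild type (14) or mutant (9), or Kdm4d, wild type (12) or mutant (10), or were kept in aphidicolin (9) or DMSO (11). Isolated pronuclei with Dam-lamin B1 were paternal (15) or maternal (10). Pronuclei with Kdm5b were paternal with wild type (19) or mutant (6), or maternal with wild type (19) or mutant (13). The mean recovered depth was 232012 reads in zygotes with Dam-lamin B1 and 409980 with Dam. It was 241543 in oocytes with Dam-lamin B1 and 1188650 with Dam. The labels name no mother, litter or day, so the p-values below measure the spread between these embryos only.

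The deposited LADs of the blastocyst served as the reference for lamina contact. The ICM, which forms the embryo proper, had 460 LADs over 1405.75 Mb, and the TE, which forms the placenta, had 503 over 1435.76 Mb. In both lists the median LAD was 1.8 Mb long. They shared 1208.16 Mb, a Jaccard index of 0.740 where random placement of bins would give 0.420. Of the ICM LAD length 85.9% lay in TE LADs, and 84.1% the other way. Bins in both lists held 0.463 protein-coding genes on average and bins in neither 1.59. Of the olfactory receptor genes 944 of 1099 (85.9%) lay in bins of both lists, as did 14 of 18 long neuronal genes. None of the bins in both lists held any of 39 Hox, 63 histone or 10 housekeeping genes. The bin of the pluripotency gene Nanog lay in an ICM LAD only and that of Sox2 in a TE LAD only. The bins of Pou5f1, Cdx2 and Gata6 lay in neither. There is 1 list per tissue, so these overlaps carry no error.

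The first comparison asked whether the lamin B1 fusion gave a pattern of its own in zygotes, against Dam alone. Gene-poor regions with olfactory receptors and long neuronal genes were enriched with Dam-lamin B1, and gene-rich regions with Dam. The bin of the receptors Olfr1145, Olfr1153 and Olfr1143 (chromosome 2, 87800001 to 87900000) had an OE of 2.95 ± 1.60 (SD, n = 19) with Dam-lamin B1 and 0.455 ± 0.488 (n = 46) with Dam. The bin of Gdf9, a growth factor secreted by the oocyte, had 0.465 ± 0.495 and 1.87 ± 1.13. The bin of the glycolytic enzyme gene Gapdh had 0.576 ± 0.513 and 1.99 ± 1.21. The LAD contrast was 0.64 ± 0.26 with Dam-lamin B1 and -0.74 ± 0.15 with Dam. The difference of 1.38 (95% interval 1.26 to 1.51) had a permutation p of 1e-05, the smallest these resamples can give, and an adjusted p of 7e-05. It was seen in 19 of 19 zygotes, each above the highest Dam cell. Mean OE in bins of both LAD lists was 1.20 with Dam-lamin B1 and 0.823 with Dam, and in bins of neither 0.774 and 1.37. Pearson's r with gene density, across bins, which are not independent replicates, was -0.0691 and 0.205 (adjusted p 0.000117, 19 of 19).

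In limma, 14374 of 23969 bins differed between these groups, 5306 higher and 9068 lower with Dam-lamin B1, and Fisher's exact test called 9692. Of the bins in neither list 5694 of 7662 (74.3%) were lower, and of those in both 4120 of 12067 (34.1%) were higher. The Olfr1145 bin was higher by log2 2.35 (SE 0.297, adjusted p 1.25e-11, 19 of 19 zygotes). Khdrbs2, which encodes an RNA-binding protein (chromosome 1, 32400001 to 32500000), was higher by 2.22 (19 of 19), and of the 10 highest bins 7 held no gene midpoint. Among the lowest were the bins of Edc3 and Clk3 (chromosome 9, 57700001 to 57800000; -2.04, SE 0.262, adjusted p 2.92e-11, 19 of 19) and of Kdm4b and Uhrf1 (chromosome 17, 56300001 to 56400000; -1.96, 18 of 19). Of the 28 marker genes 18 had a called bin, 4 higher and 14 lower, and the numbers adjusted over the list alone were the same. The 4 higher were the neuronal genes Pcdh9 (2.17), Cntnap2 (1.86) and Lrp1b (1.36) and the chloride channel gene Cftr (1.12). The Pcdh9 bin was in neither LAD list. The lower ones included Gdf9 (-1.72), Gapdh (-1.55), the pluripotency gene Pou5f1 (-1.39), Lmnb1 (-1.16), the trophectoderm gene Cdx2 (-1.11) and Sox2 (-1.06). Others were the bins of Tbp, Eef1a1, Zp3, Mos, Actb, Alb and Zscan4c, at -1.13 to -0.79. Nanog (-0.53, adjusted p 0.0614) and Gata6 (-0.57, adjusted p 0.0561) missed the threshold.

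List scores separated the same constructs. With Dam-lamin B1 the scores of long neuronal genes (1.24, 95% interval 1.08 to 1.40, 19 of 19), the prolactin family (1.17, 18 of 19), olfactory receptors (0.75, 19 of 19) and vomeronasal receptors (0.58, 19 of 19) were higher, each with an adjusted p of 1.33e-05. Of 338 olfactory receptor bins 163 were higher and 41 lower, and 163 and 42 adjusted over the list alone. For the vomeronasal receptors 45 of 185 bins were higher and 13 lower (42 and 10 adjusted over the list alone). The scores of 9 lists were lower by more than 0.70 and in at least 17 of 19 zygotes. These were lamina and tethers (-1.07), clustered protocadherins (-1.03), housekeeping (-0.99), ribosomal proteins (-0.93), pluripotency (-0.90), histones (-0.86), Hox (-0.81), trophectoderm (-0.73) and oocyte genes (-0.73). Smaller decreases were found for keratins (-0.54), Zfp genes (-0.45), defensins (-0.45), primitive endoderm (-0.37, adjusted p 0.00358, 16 of 19), the marker genes (-0.29) and genome activation (-0.25, adjusted p 0.00268, 14 of 19), which did not pass at equal reads (adjusted p 0.0824). Of 71 ribosomal protein bins 57 were lower and 0 higher. Cytochrome P450 genes did not pass (0.11, adjusted p 0.157, 12 of 19), with 8 bins higher and 11 lower of 43 and a median bin at -0.21.

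**Figure D1:**
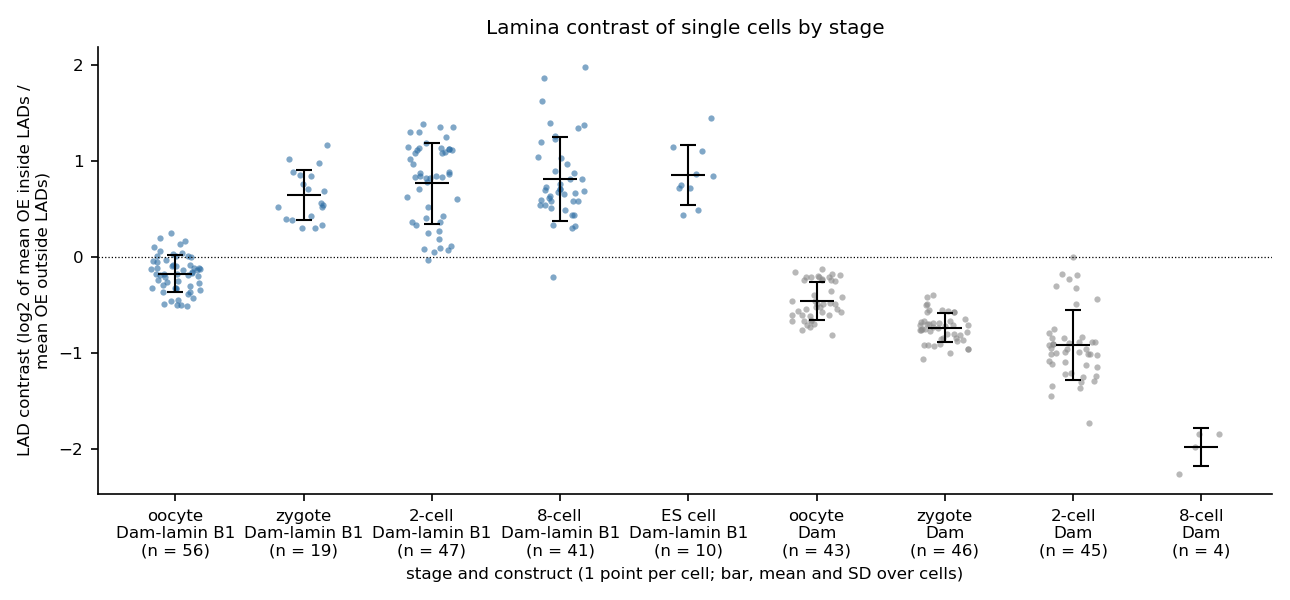
LAD contrast (log2 ratio of mean OE in bins of both LAD lists to mean OE in bins of neither) of each cell for 9 groups of stage and construct. Each point is a cell, with the mean and SD of the group; means with Dam-lamin B1 were -0.17 in oocytes, 0.64 in zygotes, 0.77 and 0.81 in 2-cell and 8-cell embryos and 0.85 in ES cells.

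The course of development asked when lamina contacts resembling those of the blastocyst appear. In oocytes, Dam-lamin B1 signal was on average not enriched in those LADs: the mean LAD contrast was -0.17 ± 0.19 (SD over 56 cells), and 12 of 56 were above 0. It was above 0 in 19 of 19 zygotes, in 46 of 47 cells at the 2-cell stage (0.77 ± 0.42), in 40 of 41 at the 8-cell stage (0.81 ± 0.43) and averaged 0.85 ± 0.31 in ES cells. With Dam alone it was -0.45 ± 0.20 in oocytes, -0.92 ± 0.36 at the 2-cell stage and -1.98 ± 0.20 in the 4 cells of the 8-cell stage. The mean profile of oocytes with Dam-lamin B1 had an r across bins of 0.668 with that of oocytes with Dam. The same r in zygotes was -0.0448. Oocytes labelled 20 ng or 50 ng had no higher contrast, at -0.24 ± 0.09 for 20 ng (17 cells) and -0.23 ± 0.09 for 50 ng (23 cells). These labels give no concentration, so they cannot be set directly against the 5 ng/µl of the main oocyte group. Single oocytes, cells of 2-cell and 8-cell embryos and ES cells come from animals, embryos or a culture that the labels do not name. Each of these groups was therefore taken as 1 sample and no test between stages was run, while zygotes, each a whole embryo, were taken as replicates in the tests. Dose and strain label differ along the course.

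**Figure D2:**
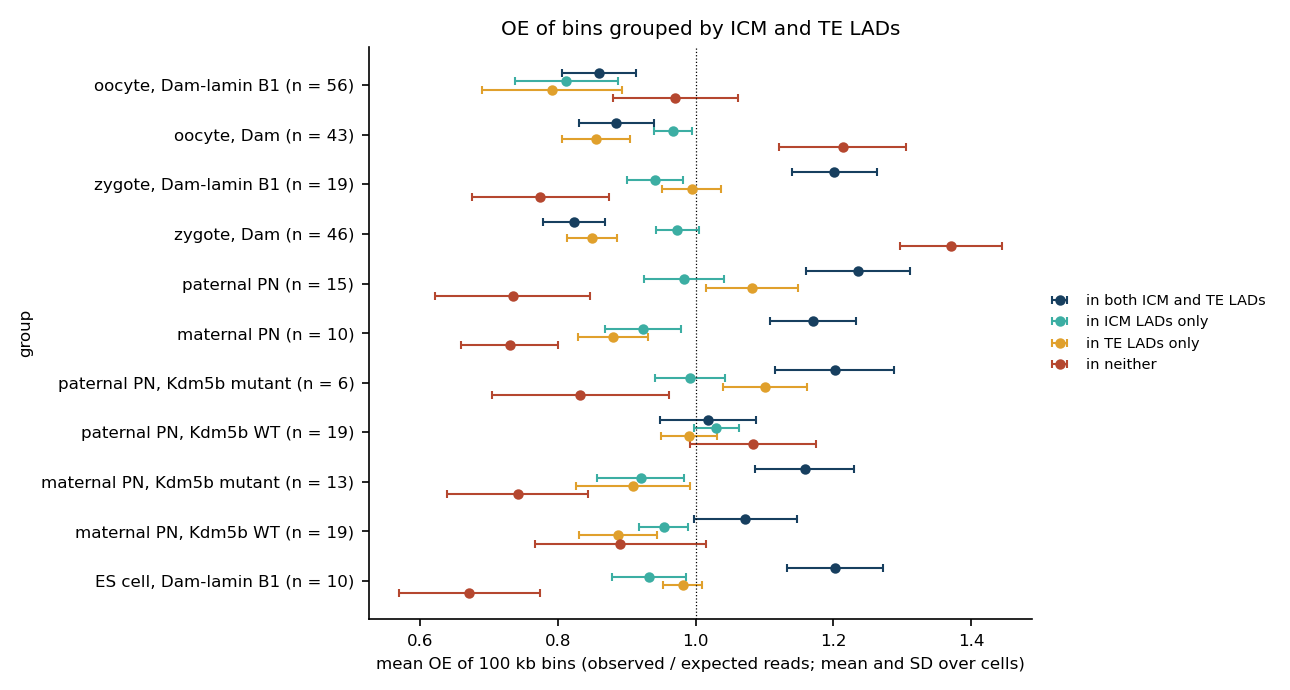
Mean OE of 11 groups in bins of both LAD lists, ICM LADs only, TE LADs only and neither list, with SD over cells. In zygotes with Dam-lamin B1 it was 1.20 in bins of both lists and 0.774 in bins of neither, and in oocytes with Dam-lamin B1 0.860 and 0.970.

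Named regions illustrate the steps of this course. For these bins, contact means an OE of at least 1 with Dam-lamin B1 and was not set against Dam. In oocytes the mean profiles of the constructs had an r of 0.668, so contact there need not be at the lamina. A bin of the olfactory receptors Olfr1182, Olfr1180 and Olfr1181 (chromosome 2, from 88400001) was in contact in 2 of 56 oocytes (3.57%, exact 95% interval 0.435 to 12.3) and in 17 of 19 zygotes (89.5%, 66.9 to 98.7). The Khdrbs2 bin was in contact in 11 of 56 oocytes (19.6%) and 19 of 19 zygotes. In the other direction, the bin of the oocyte gene Oog4 and Pramel12 was in contact in 46 of 56 oocytes (82.1%) and 2 of 19 zygotes (10.5%). The Pcdh8 bin was in contact in 40 of 56 oocytes (71.4%) and 0 of 19 zygotes, which allows up to 17.6%. The bin of Cfap53, a gene of cilia, was in contact in 0 of 47 cells at the 2-cell stage (up to 7.55%), in 35 of 41 at the 8-cell stage (85.4%) and in 0 of 10 ES cells (up to 30.8%). The bin of Pramel22, Pramel23 and Pramel21 was in contact in 4 of 47 cells at the 2-cell stage and 40 of 41 at the 8-cell stage. That of the synaptic gene Nxph1 was in contact in 44 of 47 (93.6%) and 10 of 41 (24.4%). From zygote to 2-cell stage, the bin of Ugt2b36 and Ugt2b35 was in contact in 15 of 19 and 2 of 47 cells. Over draws of 10 cells, the share of bins in contact in at least 80% of cells was 3.77% in oocytes, 6.41% in zygotes, 8.47% and 8.15% at the 2-cell and 8-cell stages and 8.69% in ES cells. With Dam alone it was 16.3% in oocytes, 11.4% in zygotes and 10.7% at the 2-cell stage, but which construct had more depends on the threshold. With contact at an OE of at least 2 it was 0.0440% with Dam and 0.0719% with Dam-lamin B1 in oocytes, 0.196% and 0.232% in zygotes and 0.812% and 0.672% at the 2-cell stage. At equal reads the gap in oocytes was smaller, 4.73% with Dam and 2.31% with Dam-lamin B1. In ES cells it was then 3.60% in ES cells, below the 4.18% of zygotes, so the order of stages depends on depth. The mean r between cells of a group was 0.143 ± 0.0633 in oocytes, 0.185 ± 0.0441 in zygotes, 0.235 ± 0.0971 and 0.254 ± 0.0923 at the 2-cell and 8-cell stages and 0.222 ± 0.0635 in ES cells. These bins were selected for their change, and contact at a fixed OE also depends on depth. The intervals take cells as independent draws. Cells that share an animal, embryo or culture are not, so the intervals are likely too narrow.

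Kdm5b removes methyl groups from histone H3 lysine 4, a mark of active promoters, and was given as mRNA to ask whether that mark bears on lamina contact. In whole zygotes, gene-rich regions and the Hox, ribosomal protein and housekeeping genes had more Dam-lamin B1 signal with wild-type than with mutant Kdm5b. Mean OE in bins outside both LAD lists was 0.906 with wild type and 0.652 with mutant, against 1.10 and 1.28 in bins of both. The LAD contrast was 0.31 ± 0.44 (n = 14) and 1.02 ± 0.60 (n = 9). Zygotes without Kdm5b lay between them, at 0.64 ± 0.26 (n = 19), and were not tested against either. The difference of -0.71 (95% interval -1.14 to -0.29) had an exact permutation p of 0.00368 (adjusted 0.00644), with 13 of 14 wild-type zygotes below the mutant mean. The r with the ES-cell profile was 0.180 with wild type and 0.266 with mutant (exact permutation, adjusted p 0.0231, 11 of 14), and at equal reads it did not pass (adjusted p 0.0507). The difference of r was -0.0859 as deposited and -0.0762 at equal reads. Mean depth was 928599 reads with wild type and 410381 with mutant. limma called 0 of 23939 bins, with 4117 at an unadjusted p under 0.05. Fisher's exact test called 0, with 1287 unadjusted. On simulated data of this size limma recovered 45 of 100 4-fold changes and 2 of 100 2-fold changes. Over 1 Mb windows limma called 110 of 2412, 94 higher and 16 lower with wild type. None of the 28 marker genes was called.

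By exact permutation tests of list scores, 9 of 20 lists were higher and 2 lower with wild-type Kdm5b in whole zygotes. At equal reads 5 were higher and 2 lower: histones (adjusted p 0.0677), trophectoderm (0.0677), primitive endoderm (0.491) and lamina and tethers (0.254) no longer passed. Hox clusters were higher by 0.88 (95% interval 0.38 to 1.49, adjusted p 0.00303) and ribosomal proteins by 0.64 (adjusted p 0.0140), each in 14 of 14 zygotes. Lamina and tethers (0.62, 14 of 14), genome activation (0.39), trophectoderm (0.69), histones (0.78), housekeeping (0.84) and primitive endoderm genes (0.80), each in 13 of 14, and protocadherins (0.84, 12 of 14) had adjusted p of 0.0140 to 0.0308. Olfactory receptors (-0.35, adjusted p 0.0175) and the prolactin family (-0.83, adjusted p 0.0184) were lower, each in 12 of 14. Adjusted over the list alone, 7 of 14 prolactin bins and 1 of 338 olfactory receptor bins were lower. Higher were 4 of 10 housekeeping, 3 of 8 histone, 3 of 8 protocadherin, 2 of 9 Hox, 1 of 71 ribosomal protein, 2 of 262 Zfp and 1 of 22 genome activation bins.

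In isolated pronuclei the same direction was found. In paternal pronuclei, LAD signal was nearly level with wild-type Kdm5b: mean OE was 1.02 ± 0.0693 in bins of both lists and 1.08 ± 0.0916 in bins of neither (SD, n = 19). With mutant Kdm5b it was 1.20 ± 0.0865 and 0.833 ± 0.128 (n = 6). The LAD contrast was -0.09 ± 0.21 and 0.54 ± 0.32. The difference of -0.63 (95% interval -0.87 to -0.37) had an exact permutation p of 3.39e-05 (adjusted 0.000119, 19 of 19). In maternal pronuclei it was 0.28 ± 0.30 (n = 19) and 0.65 ± 0.29 (n = 13). This difference of -0.38 (95% interval -0.58 to -0.18) had a permutation p of 0.00151 (adjusted 0.00352, 17 of 19). Over only the 13 wild-type pronuclei whose replicate numbers mutant ones also carry, it was -0.21 (permutation p 0.0350, not adjusted). This test was chosen after the data were seen. The size of the difference thus depends on which wild-type pronuclei are counted. Pronuclei without Kdm5b, not tested against these, were at 0.76 (paternal) and 0.68 (maternal), nearer to mutant than to wild type. Whether the effects in paternal and maternal pronuclei differ in LAD contrast depends on the measure. The difference was -0.25 with mean OE (permutation p 0.154) and -0.42 with the share of bins with OE of at least 1 (permutation p 0.0212). Any parental difference shared by wild type and mutant also enters both p-values. In paternal pronuclei r with the ES-cell profile was 0.0651 with wild type and 0.209 with mutant (exact permutation, adjusted p 0.00225, 19 of 19), and r with gene density was 0.0267 and -0.0935 (adjusted p 0.000445, 19 of 19). In maternal pronuclei r with gene density was -0.00853 and -0.0573 (adjusted p 0.0231, 14 of 19), and r with the ES-cell profile did not pass (0.0797 and 0.117, adjusted p 0.0690).

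Among bins, limma called 4 of 23967 in paternal pronuclei, all higher with wild type, and 3349 at an unadjusted p under 0.05. The direction depends on the setting: with a pseudocount of 1 it called 4 higher and 16 lower, and over 1 Mb windows 416 higher and 346 lower. The strongest held Dntt and Opalin (chromosome 19, 41000001 to 41100000; log2 2.05, limma adjusted p 0.0328, 19 of 19). Another held Sec31b, Wnt8b and Hif1an on the same chromosome (1.95, 19 of 19). With each cell thinned to the shallowest, the limma adjusted p of these 4 bins ran from 0.0562 to 0.124, and none passed. Their sizes were then log2 1.78 to 2.15, against 1.83 to 2.05 as deposited. In maternal pronuclei limma called 0 of 23942, with 2235 unadjusted. Fisher's exact test called 0 in both, with 1033 and 1140 unadjusted. On simulated data limma recovered 33 and 25 of 100 4-fold changes in paternal and maternal pronuclei. In paternal pronuclei the scores of Zfp genes (0.27, adjusted p 0.000678, 19 of 19), ribosomal proteins (0.50, 19 of 19), histones (0.60, 19 of 19), pluripotency (0.37, 18 of 19) and housekeeping genes (0.40, 17 of 19) were higher by exact permutation, and olfactory receptors (-0.36, adjusted p 0.000226, 19 of 19) and long neuronal genes (-0.45, 18 of 19) lower. In maternal pronuclei histones (0.80, adjusted p 0.00160, 18 of 19), Hox (0.71, 17 of 19), lamina and tethers (0.69), pluripotency (0.59), trophectoderm (0.53), ribosomal protein (0.34) and marker genes (0.22) were higher. Cytochrome P450 genes (-0.34, adjusted p 0.0425, 15 of 19) and olfactory receptors (-0.21, adjusted p 0.0477, 16 of 19) were lower. The median bin of the olfactory receptors was at 0.00 there, so the score rests on part of the bins.

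**Figure D3:**
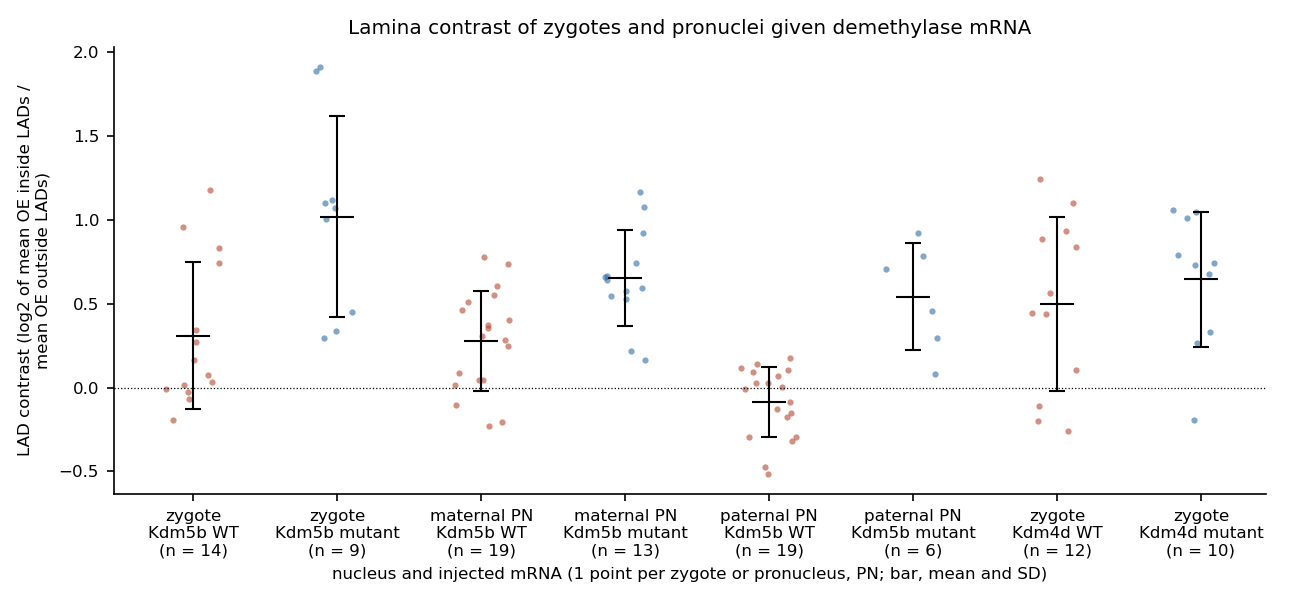
LAD contrast of each zygote or pronucleus with wild-type or mutant Kdm5b or Kdm4d, with the mean and SD of each of the 8 groups. With Kdm5b the means of wild type and mutant were 0.31 and 1.02 in whole zygotes, 0.28 and 0.65 in maternal and -0.09 and 0.54 in paternal pronuclei.

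Kdm4d removes methyl groups from histone H3 lysine 9, a mark of heterochromatin, and its mRNA posed the same question for that mark. No gene list and no marker gene passed the threshold between wild-type and mutant Kdm4d in whole zygotes. The LAD contrast was 0.50 ± 0.52 (n = 12) and 0.65 ± 0.40 (n = 10). The difference of -0.15 had a 95% interval of -0.51 to 0.23 and a permutation p of 0.468 (7 of 12 below the mutant mean). The smallest adjusted p of the 20 lists was 0.948. limma called 1 of 23930 bins, on chromosome 2 (177000001 to 177100000), without a gene midpoint (log2 2.43, adjusted p 0.000231, 12 of 12), with 949 at an unadjusted p under 0.05. Fisher's exact test called 0, with 587 unadjusted. On simulated data of this size limma recovered 46 of 100 4-fold changes. The Kdm5b effect minus the Kdm4d effect, a test chosen after the data were seen, was -0.56 in LAD contrast (permutation p 0.0645), so the effects were not shown to differ.

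Aphidicolin inhibits the DNA polymerases of replication and was compared with its solvent DMSO, to ask whether lamina contacts in zygotes need replication. The LAD contrast was 0.71 ± 0.25 (n = 9) with aphidicolin and 0.68 ± 0.47 (n = 11) with DMSO. The difference of 0.04 had a 95% interval of -0.27 to 0.34 and an exact permutation p of 0.837. None of the 20 lists passed (smallest adjusted p 0.660), the Zfp genes coming closest with -0.14 in 8 of 9 zygotes. limma called 1 of 23929 bins, which holds Gm17353 and Gm46425 (chromosome 13, 65900001 to 66000000; -2.32, adjusted p 0.00965, 9 of 9), with 1327 at an unadjusted p under 0.05. Fisher's exact test called 0, with 596 unadjusted. On simulated data limma recovered 35 of 100 4-fold changes.

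Paternal and maternal pronuclei, which carry the genomes of sperm and egg, were compared to ask whether the parental genomes differ in lamina contact. As lists, Zfp genes and genes of genome activation had less lamina signal in paternal pronuclei, and the prolactin family had more. The LAD contrast itself was 0.76 ± 0.29 (n = 15) in paternal and 0.68 ± 0.21 (n = 10) in maternal pronuclei. This difference of 0.08 had a 95% interval of -0.12 to 0.26 and a permutation p of 0.469. The bins in TE LADs only had a mean OE of 1.08 ± 0.0667 in paternal and 0.880 ± 0.0511 in maternal pronuclei. The r with the ES-cell profile was 0.228 ± 0.0802 and 0.141 ± 0.0482 (adjusted p 0.0220, 12 of 15). With equal reads that r no longer passed (adjusted p 0.0577). Mean depth was 539855 and 320312 reads. As deposited, the share of bins with OE of at least 1 was 38.8% in paternal and 35.4% in maternal pronuclei (permutation, adjusted p 0.0243, 13 of 15). The r with gene density was -0.129 and -0.0696 (adjusted p 0.0220, 12 of 15). Zfp genes had a lower score by -0.40 (95% interval -0.52 to -0.27, permutation p 1e-05, adjusted 0.000200, 15 of 15). The median Zfp bin differed by -0.04 and 3 of 263 were called, so this score rests on part of the bins. Genome activation was lower by -0.61 (-0.98 to -0.28, adjusted p 0.00430, 15 of 15) and the prolactin family higher by 1.16 (0.32 to 2.00, adjusted p 0.0393, 14 of 15).

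In limma 511 of 23964 bins differed between paternal and maternal pronuclei, 443 higher and 68 lower in paternal ones, with 3913 at an unadjusted p under 0.05. Fisher's exact test called 0, with 2270 unadjusted. On simulated data limma recovered 8 of 100 4-fold changes. Of the bins in TE LADs only 110 of 2270 (4.85%) were higher, against 61 of 7663 (0.796%) in neither list. The bin of Trp53i11 (chromosome 2, 93100001 to 93200000) had an OE of 1.83 ± 1.04 in paternal and 0.153 ± 0.265 in maternal pronuclei (log2 2.41, SE 0.482, adjusted p 0.00544, 15 of 15). That of Cps1, an enzyme of the urea cycle (chromosome 1, 67100001 to 67200000), was higher by 2.29 (14 of 15). Lower bins held Dync2h1 (-2.14, 14 of 15), the glutamate receptor gene Gria4 (-2.11, 15 of 15), Arhgap20 (-2.10, 15 of 15), Trim33 (-1.98, 15 of 15) and Vmn2r18 (-1.87, 15 of 15). Of the 10 lowest bins 5 lay on chromosome 9. Adjusted over the list alone, 3 of 263 Zfp and 1 of 187 vomeronasal receptor bins were lower, and 4 of 338 olfactory receptor, 1 of 32 keratin and 3 of 18 long neuronal bins higher. Of the 28 marker genes 0 were called over all bins and 2 adjusted over the list alone. The median difference over bins was 0.35 in TE LADs only, 0.20 in both lists and 0.15 in neither, so on this log scale most bins leaned towards the paternal side. Mean OE in bins of neither list was 0.734 ± 0.112 in paternal and 0.730 ± 0.0706 in maternal pronuclei, so the lean there is not one of mean signal. The maternal pronuclei were also the shallower group. The olfactory receptor score (-0.01) and its median bin (0.19) differ in sign. With each cell divided by its own mean OE, 312 bins were higher and 70 lower. With 45000 reads drawn from each cell, 30 bins were called.

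**Figure D4:**
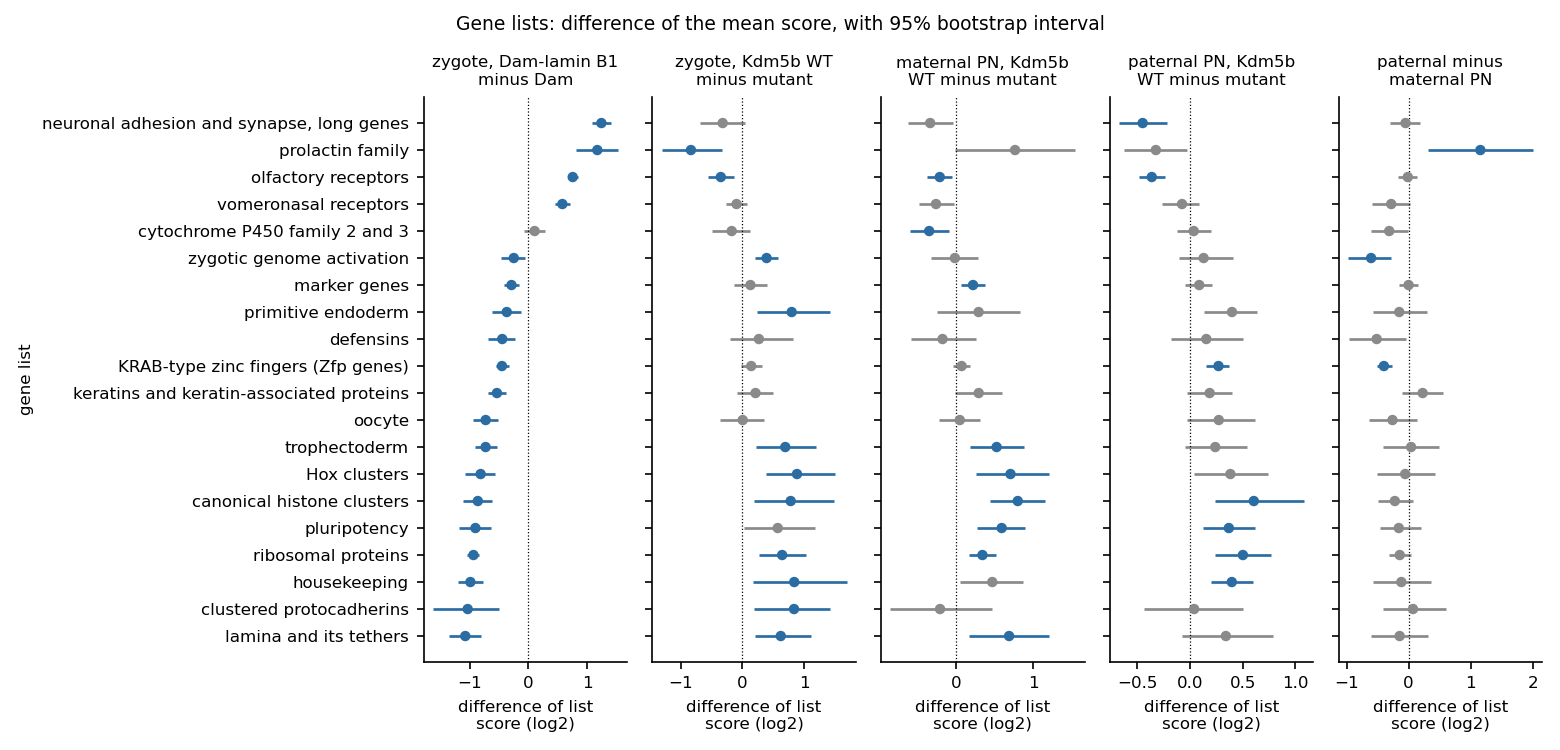
Difference of list score (log2) with its 95% bootstrap interval for 20 gene lists in 5 comparisons; blue marks an adjusted p under 0.05, and each panel has its own scale. Long neuronal genes differ by 1.24 between Dam-lamin B1 and Dam, and Zfp genes by -0.40 between paternal and maternal pronuclei.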

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

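The tests of depth and of Dam-like signal for Kdm5b, those for oocytes, the size of the parental bins at equal reads, and the parental differences of the Kdm5b effect in 3 further measures were chosen after the results were seen.

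The effect of Kdm5b differed between paternal and maternal pronuclei in 3 of the measures other than the LAD contrast. It did not in the share of bins with OE of at least 1 (permutation p 0.499) or the autocorrelation at lag 1 (permutation p 0.280) or lag 10 (permutation p 0.103). With wild-type Kdm5b, r with the ES-cell profile was lower by 0.144 in paternal and by 0.0378 in maternal pronuclei, a difference of -0.106 (permutation p 0.00281, adjusted 0.0197). At equal reads it was -0.0918 (adjusted p 0.00385). The effects on r with gene density differed by 0.0714 (permutation p 0.0117, adjusted 0.0401), and at equal reads the adjusted p was 0.135. The effects on r with the mean profile of zygotes with Dam differed by 0.134 (permutation p 0.0172, adjusted 0.0401), and at equal reads by 0.0416 (adjusted p 0.492). Only the first of these 3 passed at equal reads. Any parental difference shared by wild type and mutant also enters these p-values. No explanation of this difference was tested.

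Of the cells outside the groups only 1 had a LAD contrast above 0. The cell of an 8-cell embryo whose labels name both constructs had a LAD contrast of 0.71. The 13 oocytes with contradictory doses had a median LAD contrast of -0.27 (range -0.36 to -0.21). All 13 lay above the median of oocytes with Dam (-0.49) and 0 above the highest of these (-0.13). The medians of oocytes labelled 20 ng and 50 ng were -0.27 and -0.24.

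The first pattern weighed was the lower LAD contrast with wild-type than with mutant Kdm5b. On depth as its cause, the difference at equal reads was -0.71 in whole zygotes (exact permutation p 0.00421), -0.38 in maternal (permutation p 0.00114) and -0.62 in paternal pronuclei (exact permutation p 3.95e-05). Drawing reads at random hardly moves a ratio of mean OE over many bins, so this outcome was nearly fixed beforehand. It shows only that the number of reads drawn does not shift this measure, and decides nothing about what else goes with depth. Against a few bins of very high OE, capping OE at 5 left -0.70 in whole zygotes, -0.35 in maternal and -0.63 in paternal pronuclei. A loss of lamin-specific signal in favour of the kind that Dam alone gives stays open. Outside both LAD lists, r with the zygote Dam profile at equal reads was higher with wild type by 0.112 in maternal pronuclei (permutation p 0.0013), by 0.103 in whole zygotes (exact permutation p 0.0807) and by -0.0263 in paternal pronuclei (exact permutation p 0.512). So a lower contrast may reflect weaker lamina contact, or a larger share of contact-independent methylation. The latter predicts a higher r with wild type, which passed in maternal pronuclei only. In paternal pronuclei the difference lay below 0 and did not decide. Weaker lamina contact could raise this r as well, so it cannot separate these readings. Zygotes without Kdm5b, at 0.64, lay between wild type and mutant, so the gap in whole zygotes may in part be a higher contrast with mutant; this was not tested.

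Chance as the source of bin counts was tested by redrawing the groups in 100 splits, the real one included. For Kdm5b in whole zygotes (highest other 3) and maternal pronuclei (highest other 5) the real split called 0 bins, so all 100 splits call as many whatever the data, and this count says nothing about chance. In paternal pronuclei 2 of 100 called as many as the real 4 (highest other 8), and 23 redrawn splits called any bin. That share lies under 0.05, but it rests on few splits and is not adjusted over the comparisons. Chance is therefore not excluded for these bins. Over 1 Mb windows only the real split called as many in whole zygotes (110, highest other 1) and maternal pronuclei (9, highest other 1). That is the smallest share these splits can give, and it is not adjusted over the comparisons. It weighs the number of windows called, so chance is not excluded for any single window. In paternal pronuclei only the real split called as many as 762 windows. The highest other split called 687, and it kept 5 of the 6 mutant pronuclei together, so it nearly repeats the real groups. The bin called with Kdm4d was matched by 9 of 100 splits (highest other 2) and that with aphidicolin by 44 of 100 (highest other 4), so chance is not excluded for either. For Dam-lamin B1 against Dam, 1 of 100 splits, the real one, called 14374 bins and the highest other 9.

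The second pattern was the LAD contrast below 0 in oocytes with Dam-lamin B1. At equal reads the mean was -0.17 ± 0.19, but drawing reads hardly moves this measure, so depth as its cause was not decided. Against too little construct as the cause of the whole pattern, oocytes labelled 50 ng had a mean of -0.23 ± 0.09, with 0 of 23 above 0, and those labelled 20 ng -0.24 ± 0.09. The protocol gives the main oocyte group and zygotes the same dose, 5 ng/μl, and at that dose zygotes reached 0.64. The labels of 20 and 50 ng give no concentration, so how far they exceed 5 ng/μl is not known. The amount of protein made was not measured. A first test, the difference of 0.0158 between 50 and 20 ng, was less than the SD over cells, decided nothing, and was replaced by this one. A biological state of the oocyte in which lamin B1 does not sit at these LADs was not tested.

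The third pattern was the set of 511 bins that differ between paternal and maternal pronuclei. Only the real split of 100 called as many (highest other 4), the smallest share these splits can give and not adjusted. It weighs the number of bins, so chance is not excluded for any single bin. At equal reads 5.48% of the bins were still called in the same direction, under the bound set beforehand for depth as the cause, and 34.1% when each cell was thinned to the shallowest one. At equal reads 510 of 511 bins had the same sign, and the median size was log2 1.65 (lower quartile 1.43) against 1.71 as deposited. These reads are a subset of those that picked the bins, so sign and size tend to persist. The sizes therefore cannot decide whether a difference in depth is the cause. The median SE went from 0.481 to 0.585, so calls ended with lower precision more than with smaller size, and the bound on calls could not separate precision from size. Which bins pass therefore depends on depth, and sizes of bins picked for a difference are likely too large.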

How the results depend on the processing

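Drawing equal reads, thinning to the shallowest cell and taking the cells of the block without it were chosen after the results were seen. The LAD contrast of Dam-lamin B1 against Dam, and of Kdm5b in whole zygotes and in paternal pronuclei, kept its direction and its side of the threshold under every setting run. Settings that changed a result follow, though not every such change is listed, and the cause was not tested unless stated.

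For differences that had not passed, the sign depended on the setting. The aphidicolin difference in LAD contrast was -0.0831 with the share of bins with OE of at least 1 in place of mean OE (exact permutation p 0.732). The paternal minus maternal difference was -0.00723 with ICM LADs only (permutation p 0.925). With the share of bins, the Kdm5b effect differed between paternal and maternal pronuclei by -0.42 (permutation p 0.0212), a call not made with mean OE; the cause was not tested. With that share, the LAD contrast was 1.24 in ES cells, -0.74 in oocytes with Dam, -1.76 in 8-cell embryos with Dam and -0.33 in oocytes labelled 50 ng.

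Replicate numbers were also taken as blocks, although nothing in the labels says that equal numbers pair samples. Pairs correlated above 0.1 in at most 2 of 9 cases in a comparison. Paired by number, the Kdm5b difference of maternal pronuclei in LAD contrast was -0.21 over 13 pairs (permutation p 0.0725). The same cells, not paired, gave -0.21 and a permutation p of 0.0350. The smaller size therefore came with which wild-type pronuclei were left out, not with pairing. Neither p was adjusted over the 7 comparisons, so whether the call ended only with pairing is not shown. With blocks limma called 2 bins for aphidicolin, 140 between parental pronuclei and 0 for Kdm5b in paternal pronuclei. The same cells without the block gave 145 for the parental pronuclei and 0 for Kdm5b, so the loss there came with the fewer cells.

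Counts of bins depended on the test and the window. Over 1 Mb windows, of which there are fewer to test, limma called 1967 for Dam-lamin B1 against Dam, 110 for Kdm5b in whole zygotes, 9 in maternal and 762 in paternal pronuclei, 219 between parental pronuclei, and 0 for Kdm4d and 0 for aphidicolin. Fisher's exact test called 0 in each comparison but the first, including Kdm4d, aphidicolin, parental pronuclei and Kdm5b in paternal pronuclei. With the group sizes of aphidicolin and of Kdm5b in paternal pronuclei, no bin on its own could pass it after adjustment. The 0 in these comparisons therefore says little. Its unadjusted counts stand beside the results. With a pseudocount of 0.05 limma called 0 for aphidicolin and 13 for Kdm5b in paternal pronuclei, and with a pseudocount of 1 it called 20 there and 270 between parental pronuclei. At equal reads it called 0 for Kdm4d, 0 for aphidicolin, 30 between parental pronuclei, 1 for Kdm5b in maternal and 0 in paternal pronuclei. Thinned to the shallowest cell of both groups, it called 3 for Kdm4d, 200 between parental pronuclei and 0 for Kdm5b in paternal pronuclei. Apart from the fewer windows, the cause was not tested. The direction of the calls for Dam-lamin B1 against Dam was split as 5306 higher and 9068 lower, as 4570 and 5122 by Fisher's exact test, and as 4643 and 5594 at equal reads.

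Contact frequency moved with its threshold and with depth, as its construction requires. With contact at an OE of at least 0.5, the share of bins in contact in at least 80% of cells was 22.6% in oocytes, 31.1% in zygotes, 27.5% in 2-cell, 30.1% in 8-cell and 43.6% in ES cells with Dam-lamin B1, and 69.6% in oocytes, 44.3% in zygotes and 34.2% in 2-cell with Dam. With contact at an OE of at least 0.5, the share of bins in contact in at most 20% of cells was 13.8% in oocytes, 3.84% in zygotes, 10.3% in 2-cell, 8.09% in 8-cell and 2.45% in ES cells with Dam-lamin B1, and 2.40% in oocytes, 4.01% in zygotes and 6.26% in 2-cell with Dam. With contact at an OE of at least 2, the share of bins in contact in at least 80% of cells was 0.0719% in oocytes, 0.232% in zygotes, 0.672% in 2-cell, 0.823% in 8-cell and 0.171% in ES cells with Dam-lamin B1, and 0.0440% in oocytes, 0.196% in zygotes and 0.812% in 2-cell with Dam. With contact at an OE of at least 2, the share of bins in contact in at most 20% of cells was 85.1% in oocytes, 77.6% in zygotes, 75.2% in 2-cell, 77.8% in 8-cell and 86.6% in ES cells with Dam-lamin B1, and 94.9% in oocytes, 82.5% in zygotes and 78.8% in 2-cell with Dam. Over all cells instead of 10, the share of bins in contact in at least 80% of cells was 0.370% in oocytes, 1.73% in zygotes, 3.18% in 2-cell, 3.33% in 8-cell and 8.69% in ES cells with Dam-lamin B1, and 7.39% in oocytes, 4.38% in zygotes and 5.62% in 2-cell with Dam. Over all cells instead of 10, the share of bins in contact in at most 20% of cells was 24.8% in oocytes, 14.6% in zygotes, 24.4% in 2-cell, 22.3% in 8-cell and 28.3% in ES cells with Dam-lamin B1, and 19.4% in oocytes, 17.7% in zygotes and 21.3% in 2-cell with Dam. At equal reads, the share of bins in contact in at least 80% of cells was 2.31% in oocytes, 4.18% in zygotes, 4.94% in 2-cell, 5.02% in 8-cell and 3.60% in ES cells with Dam-lamin B1, and 4.73% in oocytes, 4.87% in zygotes and 5.72% in 2-cell with Dam. At equal reads, the share of bins in contact in at most 20% of cells was 40.0% in oocytes, 33.8% in zygotes, 39.9% in 2-cell, 36.1% in 8-cell and 31.7% in ES cells with Dam-lamin B1, and 28.5% in oocytes, 31.1% in zygotes and 34.4% in 2-cell with Dam.

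The similarity of cells moved likewise. With Spearman's rho, the mean correlation between cells was 0.191 in oocytes, 0.155 in zygotes, 0.237 in 2-cell, 0.215 in 8-cell and 0.197 in ES cells with Dam-lamin B1, and 0.328 in oocytes, 0.236 in zygotes, 0.239 in 2-cell and 0.423 in 8-cell with Dam. Over 1 Mb windows, the mean correlation between cells was 0.202 in oocytes, 0.383 in zygotes, 0.396 in 2-cell, 0.443 in 8-cell and 0.395 in ES cells with Dam-lamin B1, and 0.452 in oocytes, 0.501 in zygotes, 0.566 in 2-cell and 0.815 in 8-cell with Dam. At equal reads, the mean correlation between cells was 0.102 in oocytes, 0.139 in zygotes, 0.173 in 2-cell, 0.182 in 8-cell and 0.122 in ES cells with Dam-lamin B1, and 0.110 in oocytes, 0.160 in zygotes, 0.213 in 2-cell and 0.412 in 8-cell with Dam. Depth limits it: the r of oocytes with Dam, the deepest group, was 0.287 as deposited.

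List calls also changed at equal reads. For Kdm5b the lists higher and lower went from 9 and 2 to 5 and 2 in whole zygotes, from 7 and 2 to 8 and 4 in maternal and from 5 and 2 to 6 and 3 in paternal pronuclei. For Dam-lamin B1 against Dam they went from 4 and 15 to 4 and 14. Calls on measures per cell changed too. With wild-type Kdm5b in whole zygotes the autocorrelation was lower at lag 1 (exact permutation, adjusted p 0.110 as deposited, 0.0357 at equal reads) and lag 10 (0.0954 and 0.0323). The share of bins with OE of at least 1 went from 0.0231 to 0.0501. In paternal pronuclei both lags were lower as deposited (adjusted p 0.0118 and 0.00389). The cause was not tested.

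At equal reads some differences that had not passed changed sign, and none passed there. For Kdm4d these were the scores of keratins (0.0343), Hox (-0.26), cytochrome P450 (-0.0422), pluripotency (-0.10) and marker genes (0.0118) and the share of bins with OE of at least 1 (-0.363). For aphidicolin they were keratins (-0.0885) and the prolactin family (-0.0528). Between parental pronuclei they were protocadherins (-0.20), long neuronal (0.0929), trophectoderm (-0.0616) and marker genes (0.0213) and the lag-1 autocorrelation (-0.0592). For Kdm5b in whole zygotes it was the oocyte list (-0.000984). For Dam-lamin B1 against Dam they were the autocorrelations at lag 1 (0.0274) and lag 10 (0.0168). The cause was not tested.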

Other observations

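No cell was treated as a duplicate of another. The highest Pearson's r between any pair of cells, over 130816 pairs, was 0.763, between cells of 8-cell embryos.

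Oocytes with Dam-lamin B1 had a mean autosomal OE of 0.885 ± 0.0336 (SD over cells), while those labelled 20 ng had 0.978 and those labelled 50 ng 0.980. Paternal pronuclei had 1.04 ± 0.0219 and maternal pronuclei 0.982 ± 0.0204.

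The mean profile of paternal pronuclei with wild-type Kdm5b had an r across bins of 0.529 with that of zygotes with Dam, and of 0.206 with that of paternal pronuclei with mutant Kdm5b. Per cell, in a test chosen after the results were seen, r with the zygote Dam profile was 0.190 with wild type and -0.0655 with mutant (exact permutation p 5.65e-06, the smallest this design can give). Each of the 19 wild-type pronuclei lay above the highest mutant one. At equal reads the means were 0.117 and -0.0304 (exact permutation p 0.000288), and 7 of 19 lay above the highest mutant one. Zygotes with Dam have low OE in LADs, so over all bins this r in part restates the LAD contrast. Outside both LAD lists, at equal reads, it was 0.160 with wild type and 0.187 with mutant (exact permutation p 0.512).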
